A study of Zea mays with 6 samples.

How the data were processed

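Root samples of maize grown with peanut (3 samples) and of maize grown alone (3 samples) were hybridised as biotin-labelled cRNA, made from total RNA extracted with TRIzol, to single-colour Affymetrix maize genome arrays. The group of each sample was taken from its treatment label and its number from its title. The labels also name a peanut monoculture, which was not analysed here.

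The deposited series table holds an intensity for each probe set and array on a linear scale, which the authors had already summarised and scaled. Its medians were nearly equal on all arrays, at 134 to 142. The submitters' processing notes name GCOS 1.4, the Affymetrix operating software. The summary algorithm and the scaling target are not given in the sources used here. A scaled signal removes differences in overall brightness, so a change of all transcripts in one direction cannot be seen in these values. The authors' filtered table holds log2 values of 12255 probe sets, which equalled log2 of the deposited intensities with a largest difference of 3.6e-15, and each of them had an intensity of at least 50 on at least 3 arrays. The authors' SAM output gives, per the file headers, a score for each probe set (the log2 difference over its spread plus a constant of 0.0790), the log2 difference itself, a fold change as a linear ratio of intercropped over monocropped, and a q-value as a percent. Per the file headers it was an unpaired comparison of 2 classes with 100 permutations. The log2 differences in the authors' deposited table and those computed here were equal over the 12252 probe sets in both (largest difference 8.9e-15).

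Of 17734 probe sets, 179 controls were left out, namely the AFFX set and also the reporter (RPTR) set, which the design written at the start had not named. Intensities below 1 were set to 1, and log2 was taken with no further normalization. A probe set was tested if its intensity was at least 50 on at least 3 of the 6 arrays, whichever group these were in, which left 13116. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend=TRUE), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested, and a probe set was called at an adjusted p under 0.05. A signed difference is intercropped minus monocropped, and its standard error is the moderated one of limma. Mean signals are arithmetic means of the intensities with their SD over 3 arrays. The median standard error of a log2 difference was 0.18.

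Names came from the array annotation and from the gene column of the authors' filtered table. Of the 17734 probe sets, 1779 had 1 gene, 34 several and 15921 none. A gene ID in the reference gene table (assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone and for no coordinates) was found for 1509 of the 1779. A title naming a protein was found for 3019 probe sets, 1689 of them without a gene, often from similarity to an Arabidopsis protein that the annotation grades as weak or moderate, and these are described as similar to that protein. The annotation is old, and probe sets with neither a gene nor such a title, 14232 in all, stay unnamed here. Probe sets with a title and no gene symbol count by themselves, so that 1 transcript cluster can appear more than once.

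The gene lists, the rule for named genes, the tests and nearly all alternatives (the exceptions are named below) were fixed before the data were examined. The 35 lists, defined by expressions on symbols and titles, covered nutrient uptake, hormones, defence, cell wall, stress, transcription factors, and markers of green and of dividing tissue. Of the matches, 56 were removed for what their names say, such as a word matched inside another word, which left 1 list with no measured member; this was done after the tables were opened and by name alone. A gene counted once per list, through its probe set with the highest mean log2 signal. Lists with at least 5 measured members, 32 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other probe sets. Members were also adjusted over the list alone, with no correction for the number of lists.

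The rule for named genes took, among called probe sets with a gene symbol or a protein title and with groups that did not overlap, the 10 largest differences in each direction. Where fewer than 5 were called, it took the 10 with the smallest p in each direction, as values. Here too a probe set needed such a name and groups that did not overlap. The rule also took for each list the 2 members with the smallest p where none was called, and all members of the iron acquisition list. Genes outside the rule are marked in the text as picked after their values were seen.

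The alternatives were quantile normalization, equal array medians, no filter, a filter at a mean log2 signal of that of 100, the authors' filtered probe sets, log2 of the signal plus 32, eBayes with trend=FALSE, the replicate number as a block, each array left out in turn, and SAM on log2 and on linear signals at a false discovery rate of 5%. SAM was rewritten in R, and 20 permutations, all that 6 arrays allow, were used. For the lists, camera with an estimated correlation, fry, and all matching probe sets of a gene were added. The alternative without both arrays numbered 1, and the estimated correlation for the iron list where 5 probe sets were left in it, were chosen after the data were seen. So were 2 tests that split the estimated correlation of camera from its degrees of freedom, which fall to the 4 of the residuals. An estimated correlation below 0 was taken as 0. No pair of arrays held identical values. Correlations of the log2 signals were 0.932 to 0.956 between intercropped arrays, 0.948 to 0.970 between monocropped arrays and 0.912 to 0.954 between groups.

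The test was tried on simulated data drawn independently for each of 13116 probe sets, with the real means and with spreads as moderated by limma. In 20 simulations of intercropped against monocropped roots with 200 changed probe sets of mixed size, it recovered 65.7% of 2-fold, 97.7% of 4-fold and 99.5% of 8-fold changes, with a mean of 11 false calls. A list of 20 members shifted by 0.4 on the log2 scale was found in 100% of simulations, and 0% of 30 lists without a shift were called. Real members of a list vary together, and real arrays differ in ways that many probe sets share, which these simulations leave out. Moderated spreads also differ less between probe sets than observed ones. The shares recovered may therefore be too high for the real arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots.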

Results

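RNA levels were measured in roots of maize (Zea mays, cultivar Nongda108) that had reached the reproductive stage in a greenhouse, on a calcareous sandy soil with basal fertilizer. The plants had grown either together with peanut (cultivar Luhua14), called intercropping, or as maize alone, called monocropping. Each group had 3 samples, and each sample was hybridised to 1 Affymetrix maize genome array with 17734 probe sets, a probe set being a group of short probes against 1 transcript. The median signal was between 134 and 142 on the 6 arrays, and between 25.4% and 27.7% of probe sets had a signal below 50. Nothing in the sources used here states that the samples came from separate plants or pots, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.18.

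The comparison asked which transcripts of maize roots differed between plants grown with peanut and plants grown alone. In intercropped roots, the genes of ethylene synthesis and response, the pathogenesis-related proteins and the genes of fermentation were shifted to lower signals as groups. The list of dehydrins, LEA proteins and water stress, and the list of cellulose and wall polymers, were shifted to higher signals. These are calls on gene lists by limma's camera with a preset inter-gene correlation, and each of these 5 lists lost its call with an estimated one (adjusted p = 0.544 to 0.708 with an estimated correlation). That test has 4 degrees of freedom, and with 4 the preset correlation also gave 0 calls (lowest adjusted p = 0.16). With the estimated correlations and the degrees of freedom of the preset test, only the fermentation list was called (adjusted p = 0.00502), with ethylene at 0.0615 and the other 3 lists at 0.367. The estimated correlation of the fermentation list was below 0 and was taken as 0, which is more lenient than the preset one. These last tests were chosen after the data were seen. The members of these groups named below differed between the group means of log2 signal by 1.41-fold to 7.74-fold. The largest was that of mlg3, a gene of the dehydrin list whose intercropped signals ran from 114 to 980. No single probe set passed the test, so the signals of single genes are given below as values. Of 35 gene lists, 32 had at least 5 measured members, and limma's camera with a preset inter-gene correlation of 0.01 called 9 of them, 3 higher and 6 lower. With an estimated inter-gene correlation 0 of the 9 calls held. When the 6 arrays were split so that each group of 3 mixed both treatments, camera at the preset correlation still called between 2 and 8 lists. Limma's fry, which does not compare a list with other genes, called 0 lists in a direction. Regardless of direction, fry called the peroxidases and the bHLH and bZIP factors (adjusted p = 0.00372), and the mycorrhiza and sugar lists (0.0198). It also called the jasmonate list (0.0354) and the ethylene, flavonoid, and endodermis and suberin lists (0.0376). Members of a list called in this way may differ in opposite directions. The mycorrhiza list was also defined by nodulin, blue copper and germin-like titles. Its 2 members with the smallest p were probe sets similar to germin-like proteins.

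Ethylene synthesis and response had the smallest p of all lists in camera at the preset correlation. With an estimated correlation the hypoxia and fermentation list had a smaller one (camera p = 0.0194 against 0.0445 for ethylene). Of its 12 measured members 10 were lower and 2 higher in intercropped roots, with a median log2 difference of -0.48 (camera adjusted p = 0.000315, and adjusted p = 0.544 with an estimated correlation). No member passed limma's test over all probe sets, and 4 did, all lower, when adjusted over the list alone. Such calls also occurred in lists that camera did not call, such as the glutathione S-transferases (2 higher, 1 lower) and the auxin list (2 lower). ACC oxidases carry out the last step of ethylene synthesis. The signal of ACO20 was 191 ± 41.9 in intercropped and 395 ± 87.3 in monocropped roots (mean ± SD, n = 3), a log2 difference of -1.05 ± 0.23 (SE). A probe set similar to an ACC oxidase of Arabidopsis had 92.4 ± 41.1 against 438 ± 236, a log2 difference of -2.18 ± 0.48. Both remaining calls of the 4 lay outside the rule for named genes and were picked after their values were seen. They were ACO31, with a log2 difference of -1.53 ± 0.44, and ETR2, an ethylene receptor, with -0.65 ± 0.18. For each of these 4 genes all 3 intercropped arrays were below all 3 monocropped arrays.

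Pathogenesis-related proteins and proteinase inhibitors had 36 measured members, 27 lower and 9 higher, with a median log2 difference of -0.23 (camera adjusted p = 0.0024, and adjusted p = 0.708 with an estimated correlation). Without intercropped replicate 1 the median was -0.14. Limma called 0 members over all probe sets and 2, both lower, when adjusted over the list alone. The gene uiu5(chn), an acidic class I chitinase that degrades chitin of fungal walls, had a signal of 686 ± 223 against 1620 ± 346, a log2 difference of -1.26 ± 0.25. The gene umc1246, a putative Bowman-Birk inhibitor of serine proteases, had 151 ± 67.0 against 634 ± 220, a log2 difference of -2.12 ± 0.42.

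The hypoxia and fermentation list had 16 measured members, 11 lower and 5 higher, with a median log2 difference of -0.37 (camera adjusted p = 0.00301, and adjusted p = 0.544 with an estimated correlation). The estimated correlation was -0.0157, below the preset one, so members that vary together did not end this call. Limma called 2 members when adjusted over the list alone, both lower, and 0 over all probe sets. Alcohol dehydrogenase turns acetaldehyde into ethanol when oxygen is short. The signal of adh2 was 894 ± 196 in intercropped and 1531 ± 308 in monocropped roots, a log2 difference of -0.78 ± 0.20. A probe set similar to another alcohol dehydrogenase had 996 ± 81.7 against 1404 ± 125, a log2 difference of -0.49 ± 0.12.

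Dehydrins, LEA proteins and other genes of water stress code for proteins that accumulate in drying seeds and in tissue short of water. Of 14 measured members 11 were higher in intercropped roots and 3 lower, with a median log2 difference of 0.36 (camera adjusted p = 0.00206, and adjusted p = 0.708 with an estimated correlation). The mean was larger, 0.77, because a few members differed by far more than the rest. The median was 0.57 without monocropped replicate 3 and 0.56 without intercropped replicate 1, and the 2 arrays numbered 2 lay farthest apart, with the members at 0.75 (intercropped) and -0.86 (monocropped) relative to their means over all arrays. Limma called 0 members over all probe sets and 6, all higher, when adjusted over the list alone. ERD4 had a signal of 985 ± 133 against 494 ± 105, a log2 difference of 1.01 ± 0.19. The group 3 LEA gene mlg3 had 465 ± 456 against 52.4 ± 43.5, a log2 difference of 2.95 ± 0.84, and its intercropped signals ran from 114 to 980.4. Among the other calls of this list, dhn1 and esp5 were picked after their values were seen. The dehydrin dhn1 had a log2 difference of 2.35 ± 0.70, and the embryo specific protein gene esp5 had 2.18 ± 0.71, and 1.38 without intercropped replicate 2.

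Cellulose and wall polymer synthesis had 29 measured members, 21 higher and 8 lower, with a median log2 difference of 0.39 (camera adjusted p = 0.00301, and adjusted p = 0.708 with an estimated correlation). The list was defined by names of cellulose synthases, and also by those of wall proteins such as extensins, arabinogalactan proteins and proline-rich proteins. Limma called 0 members over all probe sets and 0 when adjusted over the list alone, while 9 had an unadjusted p under 0.05, all of them higher. The median was 0.19 without monocropped replicate 2 and 0.61 without monocropped replicate 1. Relative to their means over all arrays the members were at -0.48 on monocropped replicate 2 and at 0.11 on monocropped replicate 1, beside 0.13 to 0.24 on the intercropped arrays. The signal of CesA-9, a catalytic subunit of cellulose synthase, was 1025 ± 165 against 662 ± 63.0, a log2 difference of 0.62 ± 0.15. The signal of cesa11 was 854 ± 141 against 503 ± 157, a log2 difference of 0.79 ± 0.23.

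**Figure D1:**
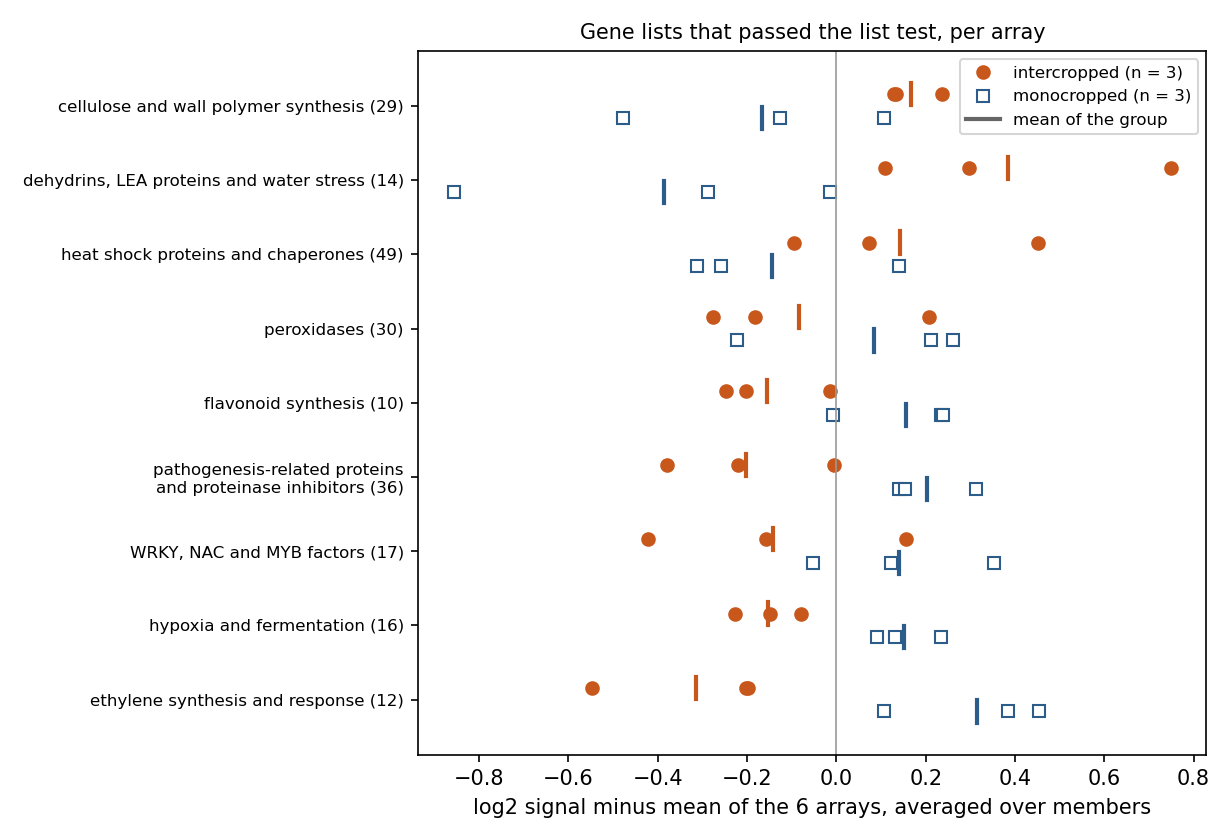
Shift of the 9 called gene lists on each array, as the log2 signal of each member minus its mean over the 6 arrays, averaged over the members of the list (the number of members is in brackets). Filled circles are the 3 intercropped arrays, open squares the 3 monocropped arrays and bars the group means. The ethylene list lay between -0.55 and -0.20 on the intercropped arrays and between 0.11 and 0.45 on the monocropped arrays.

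The 30 measured peroxidases, enzymes of the wall and vacuole that oxidise phenolic compounds, did not move as 1 group. Their median log2 difference was 0.01, with 16 members higher and 14 lower, while the mean was -0.17 and camera gave the direction down (adjusted p = 0.0398, and adjusted p = 0.708 with an estimated correlation). The median turned to -0.02 after quantile normalization and to -0.02 with array medians set equal, and with 1 array left out it ran from -0.19 (without intercropped replicate 1) to 0.0335 (without monocropped replicate 1). Adjusted over the list alone, limma called 5 members, all lower, and over all probe sets 0. A pair of probe sets from 1 transcript cluster, similar to a peroxidase of Arabidopsis, had signals of 485 ± 86.7 against 1251 ± 195 and of 100 ± 34.8 against 378 ± 49.1, log2 differences of -1.37 ± 0.18 and -1.97 ± 0.26. The anionic peroxidase H had 34.8 ± 12.1 against 143 ± 19.6, a log2 difference of -2.10 ± 0.29, whose size is uncertain because all its intercropped signals lay below 50. The remaining calls were a probe set similar to peroxidase ATP4a, with -1.42 ± 0.24, and a peroxidase R15 (LOC541672), picked after its value was seen, with -1.84 ± 0.35. The camera call of this list was lost with array medians set equal (adjusted p = 0.0682) and with no filter on dim probe sets (0.111). It was also lost without intercropped replicate 2 (0.0778) or 3 (0.3) and without monocropped replicate 1 (0.149) or 3 (0.0747), and without both arrays numbered 1 (0.0576).

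The 3 remaining called lists held less firmly than the 5 named first. Flavonoid synthesis had 9 of 10 members lower, with a median log2 difference of -0.17 (camera adjusted p = 0.0379, and adjusted p = 0.544 with an estimated correlation, which was -0.0256), and limma called 2, both lower, when adjusted over the list alone. Flavanone 3-hydroxylase makes dihydroflavonols, and the gene fht1 had a log2 difference of -1.04 ± 0.27, while a probe set similar to that enzyme had -0.83 ± 0.17. The intercropped signals of fht1 all lay below 50, where differences are least certain. WRKY, NAC and MYB transcription factors had 13 of 17 members lower, with a median of -0.25 (camera adjusted p = 0.028, and adjusted p = 0.729 with an estimated correlation), and 0 members were called by limma when adjusted over the list alone. The MYB gene c1, a regulator of anthocyanin synthesis, had a log2 difference of -0.50 ± 0.17, and a probe set similar to the WRKY factor NtWRKY4 had -1.36 ± 0.48, and -0.82 without monocropped replicate 2. Heat shock proteins and chaperones had 37 of 49 members higher, with a median of 0.13 (camera adjusted p = 0.0462, and adjusted p = 0.729 with an estimated correlation), and limma called 0 of them when adjusted over the list alone. A probe set similar to heat shock factor HSF1 had a log2 difference of 1.20 ± 0.25, and a probe set similar to a heat shock protein had -1.01 ± 0.32. The flavonoid call was lost without intercropped replicate 2 (adjusted p = 0.0785) or 3 (0.0671) and without monocropped replicate 2 (0.122) or 3 (0.053), and the call of the transcription factors without intercropped replicate 1 (0.363) or monocropped replicate 2 (0.116). The heat shock call was lost without intercropped replicate 2 (0.469) and without monocropped replicate 1 (0.149) or 2 (0.116), and with a filter at a mean signal of 100 the adjusted p of the 3 lists was 0.325, 0.2 and 0.0818. With no filter it was 0.0701 for the flavonoid list and 0.0621 for the transcription factors, in the authors' filtered probe sets 0.0503 for the transcription factors and 0.104 for the heat shock list, and with all matching probe sets 0.0954 for the heat shock list. Without both arrays numbered 1 it was 0.224 for the transcription factors and 0.0553 for the heat shock list. With 1 array left out the medians ran from -0.25 to -0.11 for the flavonoid list, from -0.37 to -0.15 for the transcription factors and from 0.0357 to 0.18 for the heat shock list.

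Maize takes up iron by releasing phytosiderophores, chelators of the mugineic acid family made from nicotianamine, and importing the iron complex through the transporter ys1. The 4 measured genes of this pathway were too few for the main list test, and their mean log2 signals were all lower in intercropped roots by amounts that limma did not call. DMAS1, deoxymugineic acid synthase, had a signal of 861 ± 52.2 against 1052 ± 115, a log2 difference of -0.29 ± 0.12 (limma adjusted p = 0.451). The nicotianamine synthase gene nas1 had 179 ± 33.8 against 234 ± 7.77, a log2 difference of -0.40 ± 0.17 (limma adjusted p = 0.441), and -0.25 without intercropped replicate 1. The transporter ys1 had 170 ± 43.3 against 216 ± 9.52, a log2 difference of -0.37 ± 0.21 (limma adjusted p = 0.57), and -0.15 without intercropped replicate 1. A probe set similar to a nicotianamine synthase had 136 ± 8.64 against 195 ± 87.8, a log2 difference of -0.44 ± 0.29 (limma adjusted p = 0.629), which was -0.0948 without monocropped replicate 2 and -0.67 without monocropped replicate 3. Under 2 alternatives the list reached 5 probe sets and was tested. With all matching probe sets, which add a second one for nas1, all 5 were lower with a median of -0.40, and camera called the list (adjusted p = 0.00791, and adjusted p = 0.492 with an estimated correlation). With no filter, which adds nas2, all 5 were lower and the list was not called (camera adjusted p = 0.0524, and adjusted p = 0.622 with an estimated correlation). The estimated correlation was added for this list after the data were seen.

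Single genes with a name were taken only where all 3 arrays of one group were above all 3 of the other. Among these, the genes with the smallest p in each direction had limma adjusted p between 0.129 and 0.207. A transcript described as similar to ABA- and ripening-inducible proteins had a signal of 1031 ± 211 in intercropped and 320 ± 58.4 in monocropped roots, a log2 difference of 1.69 ± 0.20. The gene phyS11 codes for a phytase, which releases phosphate from phytate, and had 175 ± 18.3 against 79.6 ± 9.43, a log2 difference of 1.14 ± 0.16. The homocysteine S-methyltransferase gene HMT-2 had a log2 difference of 1.92 ± 0.28, and the beta-tubulin gene tub6 had 0.80 ± 0.12. Invertases split sucrose, and ivr2 had 407 ± 99.6 against 88.7 ± 51.7, a log2 difference of 2.38 ± 0.47. The other higher genes were the bZIP factor GBF1 with a log2 difference of 1.65, AGP2, a subunit of ADP-glucose pyrophosphorylase of starch synthesis, with 1.48, ERD4, glutathione S-transferase GST 22 with 1.00 and the D-type cyclin cycD2 with 0.68.

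On the lower side, besides the peroxidases, a probe set similar to an O-methyltransferase had a signal of 23.5 ± 4.39 in intercropped and 181 ± 90.7 in monocropped roots, a log2 difference of -2.81 ± 0.43. All its intercropped signals lay below 50, so the size of this difference is uncertain. The hypersensitive induced reaction gene hir3 had 435 ± 63.3 against 921 ± 130, a log2 difference of -1.08 ± 0.17. A carbonic anhydrase (LOC542302), which interconverts carbon dioxide and bicarbonate, had 153 ± 51.2 against 391 ± 6.96, a log2 difference of -1.41 ± 0.23. Probe sets similar to a floral nectary-specific protein, to a receptor protein kinase and to a bacterial activator of D-serine dehydratase had log2 differences of -1.71 ± 0.24, -1.36 ± 0.21 and -1.60 ± 0.22. The intercropped signals of the nectary-like probe set also all lay below 50.

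**Figure D2:**
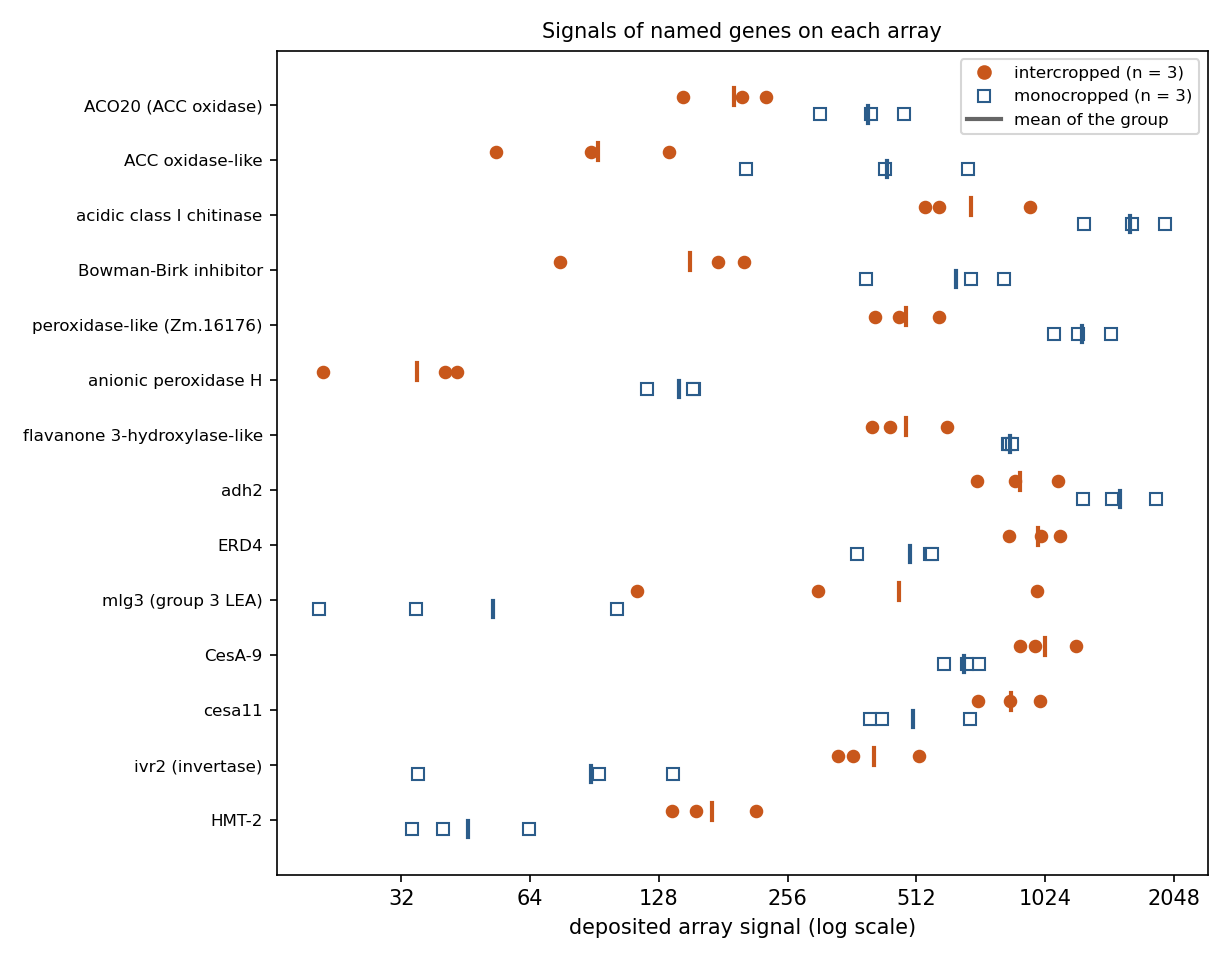
Deposited signals of 14 named genes on each array, on a log axis. Filled circles are the 3 intercropped arrays, open squares the 3 monocropped arrays and bars the arithmetic means of the groups. For anionic peroxidase H the means were 34.8 and 143, and for ivr2 they were 407 and 88.7.

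Over all 13116 probe sets tested, limma called 0 at an adjusted p under 0.05, and so 0 with at least 2-fold change. The lowest adjusted p was 0.129. At an unadjusted p under 0.05 there were 1457 probe sets, 734 higher and 723 lower in intercropped roots, where 656 are given by chance with no effect. Quantile normalization changed that division to 688 higher and 799 lower, and equal array medians to 615 higher and 839 lower. In 1087 probe sets all intercropped arrays were above all monocropped arrays, and in 1140 below, together 17.0% of the probe sets tested against the 10% that chance gives. At an unadjusted p under 0.05, a split of intercropped replicates 1 and 2 with monocropped replicate 1 against the rest gave 1750 probe sets. An excess over the values that chance gives therefore does not by itself point to the treatment. SAM, a permutation test, called 5 probe sets on log2 signals, all higher, and 3 on linear signals, all lower. The 3 were trxh2, a thioredoxin h, with a log2 difference of -0.22, and a pair of probe sets without a name, with -0.73 and -0.89. They were picked after their values were seen.

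The count of 0 depended on 1 array. Without intercropped replicate 1, limma called 34 probe sets, 12 higher and 22 lower, and 32 of the 34 had an unadjusted p under 0.05 on all 6 arrays. The calls included 5 of the single genes named above for their small p, and the ABA- and ripening-inducible-like transcript (adjusted p = 0.0482), both probe sets of the peroxidase cluster (adjusted p = 0.0407 and 0.0367) and the carbonic anhydrase (adjusted p = 0.0324) were among them. The first principal component of the log2 signals held 37.3% of the variance and had all intercropped arrays on one side of 0 and all monocropped arrays on the other. The second held 28.8%, and both arrays numbered 1 lay apart from the rest on it, at 30.1 (intercropped) and 21.6 (monocropped) against -26.8 to -1.78. Without both arrays numbered 1, an alternative chosen after the data were seen, limma called 0 probe sets and camera 9 lists, of which 6 were among the 9 called on all arrays.

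Markers of other tissue were set beside these groups. The 26 measured photosynthesis genes, markers of green tissue, had a median log2 difference of -0.02 (camera adjusted p = 0.241, and adjusted p = 0.729 with an estimated correlation). Without monocropped replicate 1, however, the list was called lower at the preset correlation (adjusted p = 0.00982, median -0.19). The median was -0.21 without intercropped replicate 3 (0.0719) and turned to 0.0738 without intercropped replicate 2 (0.725) and to 0.00535 without monocropped replicate 2 (0.528). The carbonic anhydrase above is a member of this list. The 94 histone and cell cycle genes, markers of dividing tissue, had 47 members higher and 47 lower, with a median of -0.00474 (camera adjusted p = 0.922). Above, tub6 and the probe set of cycD2 are members of this list, both higher, and limma called tub6 when adjusted over the list alone (adjusted p = 0.0221). Of the lists that were not called, jasmonate and lipoxygenase genes came nearest, with 11 of 15 members lower and a median of -0.30 (camera adjusted p = 0.0776). This list was called lower in the authors' filtered probe sets (adjusted p = 0.0464), without intercropped replicate 1 (0.0238) and without monocropped replicate 3 (0.0106). Its median was -0.18 without monocropped replicate 2, and its adjusted p rose to 0.352 without intercropped replicate 2 and to 0.708 with an estimated correlation.

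The authors' deposited table holds a SAM analysis of the same arrays. It lists 5 probe sets as higher in intercropped roots at a q-value of 0% and 0 as lower at a q-value of 5% or less, the lowest q-value on the lower side being 5.80%. The named ones among the 5 were the ABA- and ripening-inducible-like transcript and phyS11. At a q-value of 10% or less, the authors' deposited table lists 9 higher and 19 lower probe sets, and at 20% or less 152 and 178. All 28 probe sets at 10% or less had an unadjusted p under 0.05 in the same direction in limma. Both analyses used the same arrays and the same log2 differences, so this is no independent evidence. SAM on the log2 signals, run over the wider set of probe sets tested here, called the same 5.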

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

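The comparison of control probe sets with 1.5 times the highest monocropped array was chosen after these signals had been seen. Control probe sets took no part in any comparison of the report. The signal of the 18S ribosomal RNA control was 1889 on intercropped replicate 3, above the highest monocropped value of 1197. The signal of the 3' end of the actin control was 1411 on intercropped replicate 1, above the highest monocropped value of 875. The other arrays of the intercropped group had 1116 and 980 for the ribosomal control, and 693 and 602 for actin. No explanation was tested for either value.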

How the results depend on the processing

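The alternative without both arrays numbered 1, the estimated correlation for the iron list and the 2 tests on degrees of freedom were chosen after the results were seen, and the other alternatives before. Limma called 0 probe sets under every alternative on the same test except 2, so the count of 0 moved to 1 with log2 of the signal plus 32 (a probe set without a name, higher, mean signals 144 against 9.82) and to between 0 and 34 with 1 array left out, where 34 came without intercropped replicate 1. With at least 2-fold change the counts were 1 and 0 to 33. SAM called 5 probe sets on log2 signals, 4 of them with at least 2-fold change, and 3 on linear signals. A cause was not tested. All 49 named genes kept their direction in the 676 values that 14 alternatives gave, and 7 values passed the threshold, all without intercropped replicate 1. Where the groups did not overlap, as the rule for single genes required, leaving out an array cannot turn the direction. The filters, trend=FALSE and the block leave a log2 difference as it is. For such genes the kept direction is therefore no evidence of robustness.

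Camera called between 6 and 11 lists with 1 array left out, 0 with an estimated correlation and fry called 0 in a direction (lowest adjusted p = 0.139). It called 1 list with the estimated correlations at the degrees of freedom of the preset test and 0 with the preset correlation at 4 (lowest adjusted p = 0.16), so the fewer degrees of freedom alone end all calls. The cellulose, dehydrin, ethylene, hypoxia and pathogenesis-related lists had an adjusted p under 0.05 in all 15 camera alternatives with the preset correlation (trend=FALSE does not enter camera and is not counted), the highest being 0.0346, 0.00999, 0.00559, 0.0474 and 0.0231. The flavonoid and transcription factor lists did in 9, the heat shock list in 8 and the peroxidases in 7 of the 15. The photosynthesis list passed without monocropped replicate 1 (0.00982), without both arrays numbered 1 (0.0175) and with all probe sets (0.0304). The histone and cell cycle list, not called under any of these, changed the direction of its test, with medians of -0.0498 at a mean signal of 100, -0.00474 in the authors' filtered probe sets and -0.0732 without both arrays numbered 1. With 1 array left out its median ran from -0.0807 (without intercropped replicate 1) to 0.0399, and its direction also turned without monocropped replicate 2 (-0.0540). The cause was not tested.

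The replicate numbers showed no clear pairing of the samples. Deviations from the group means correlated at 0.27, -0.07 and -0.00 for the numbers 1 to 3, and 2 of the 6 arrays correlated best with their own number. A pairing is not excluded by this, as both arrays numbered 1 lay apart from the rest on the second principal component. With the replicate number as a block, limma called 0 probe sets (lowest adjusted p = 0.16) and 0 with at least 2-fold change, and camera called 9 lists, 8 of them among the 9. The block ended the call of the peroxidases (adjusted p = 0.152) and added that of the jasmonate list (0.0446). On each array 25.4% to 27.7% of probe sets lay below a signal of 50, where differences are least certain.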

Other observations

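The alternatives that leave out 1 array were fixed before the data were examined, but their use below to test an explanation was chosen after the results were seen. So were the tests of scaling, the tests with the estimated correlations at the degrees of freedom of the preset test and the test on the histone list. The soluble invertase ivr2 had a signal of 407 ± 99.6 in intercropped and 88.7 ± 51.7 in monocropped roots (mean ± SD, n = 3), while incw1, an invertase of the cell wall, had 227 ± 41.2 against 426 ± 83.8, a log2 difference of -0.91 ± 0.20. For both genes the groups did not overlap. The list of 22 sugar genes was not called (median log2 difference -0.07, camera adjusted p = 0.655), and with 1 array left out its median ran from -0.11 (without intercropped replicate 1) to 0.0154 (without intercropped replicate 2). Limma called 3 of its members when adjusted over the list alone, 1 higher and 2 lower, among them ivr2 and incw1 (adjusted p = 0.0255 for both).

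The gene pht7, a phosphate transporter, had a signal of 62.2 ± 28.9 against 205 ± 84.0, a log2 difference of -1.75 ± 0.39. Limma called pht7 when adjusted over the list alone (adjusted p = 0.0345). The list of 13 phosphate genes, 8 lower and 5 higher, was not called (median -0.18, camera adjusted p = 0.241, and adjusted p = 0.729 with an estimated correlation). At the preset correlation it was called lower without intercropped replicate 1 (0.0427, median -0.28) and without both arrays numbered 1 (0.0381, median -0.29). Without intercropped replicate 2 the median was -0.05 (0.469). The phytase gene phyS11, with a log2 difference of 1.14 ± 0.16, is not a member of it.

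The ethylene and pathogenesis-related lists were both lower in intercropped roots. Scaling between arrays is argued against as the whole cause, since the array medians of log2 signal lay within 0.0767 of each other, and after quantile normalization or equal medians the list medians were still at -0.24 or lower. A single array is argued against too, since the highest adjusted p with 1 array left out was 0.0151, although the median of the pathogenesis-related list was -0.14 without intercropped replicate 1. Members that vary together for another reason could give the same calls, and with the estimated correlations at the degrees of freedom of the preset test the adjusted p was 0.0615 and 0.367. The effect of intercropping itself stays open beside this.

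The dehydrin and water-stress list was higher in intercropped roots. Its median was still 0.33 or higher under another scaling, and its highest adjusted p with 1 array left out was 0.00999, which argues against scaling and against a single array as the whole cause, although the median moved from 0.36 to 0.57 without monocropped replicate 3. Leaving out 1 array cannot test a shift carried by 2 arrays. Those numbered 2 lay farthest apart, at 0.75 (intercropped) and -0.86 (monocropped), and were not left out together. The estimated correlation of its members was 0.31, and with it at the degrees of freedom of the preset test the adjusted p was 0.367, so members that vary together for a reason other than the treatment may account for the call. A difference in water supply between the groups was not tested, as no measure of it was analysed here.

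The cellulose and wall polymer list was higher in intercropped roots. Its median was still 0.36 or higher under another scaling, and its highest adjusted p with 1 array left out was 0.0346, although the median was 0.19 without monocropped replicate 2. For a larger share of dividing tissue in the intercropped samples, the histone and cell cycle list, which also holds tubulins, was compared. Its median log2 difference was -0.00474, which lay below the 0.39 of the wall list by more than the SD of 0.28 over its members. That SD is a spread between genes, and not the error of a median or the spread between arrays. The comparison therefore argues only against a shift of these markers as large as that of the wall list. It does not settle the share of dividing tissue. The comparison also rests on all 6 arrays, since without monocropped replicate 2 the medians lay 0.25 apart, less than the SD of 0.28. Members that vary together could account for the call, with an adjusted p of 0.367 with the estimated correlation at the degrees of freedom of the preset test.

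The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Limma called 0 probe sets in the real split and at most 1 in another, and the same held with at least 2-fold change, so that 10 of 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 1457 probe sets and the highest other split 1750, which set intercropped replicates 1 and 2 with monocropped replicate 1 against the rest, and 2 splits gave as many as the real one. Camera called 9 lists in the real split and between 2 and 8 in every other, so 1 split, the real one, gave as many. At the preset correlation camera thus also called lists in each split that mixes the groups. The rank of the real split among 10 is no evidence for an effect of the treatment.

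The hybridisation controls, bacterial transcripts added to each sample, differed between arrays. The median signal of the bioB probe sets was 1274 on monocropped replicate 1 and between 149 and 488 on the other arrays. These controls took no part in any comparison.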
